A study of Mus musculus with 10 samples.

How the data were processed

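Gene expression was measured on Affymetrix whole-transcript mouse arrays in cultures of marrow cells from young male Swiss mice. Per the labels' protocols, cells were cultured in αMEM with fetal calf serum and calcitriol, RNA was isolated with RNeasy kits and labelled with biotin through the Affymetrix whole-transcript cDNA kit. Recombinant mouse adiponectin was given at 5 µg/ml, and 1 treated and 1 control culture were taken at each of 4, 10, 24, 72 and 120 h. The deposited values are on a log2 scale, 1 value per probe set and array. RMA, which corrects background, applies quantile normalization and summarises probes by median polish, is named together with Affymetrix Expression Console and Partek, per the submitters' processing notes. Versions, the order of steps and the genome build behind the probe sets are not given in the sources used here. Quantile normalization brings arrays towards a common distribution, so much of a shift shared by most transcripts would be removed. The deposited arrays were close but not identical in distribution, with medians over all probe sets from 7.90 to 8.08.

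The table held 35556 probe sets on 10 arrays. The platform annotation gave 1 gene symbol for 21789 of them, several for 1621 and none for 12146. Symbols were checked through Entrez IDs against RefSeq (assembly GRCm38.p6, used for names only): 91 probe sets had an ID outside that table and 0 symbols changed. Probe sets with several symbols or none were named in no comparison. For the 999 genes with more than 1 probe set, the one with the highest mean over all arrays stood for the gene, which left 19938 genes. Of the genes fixed for naming, Cyp24a1, Runx2 and Bglap had no probe set of their own symbol alone and are not analysed here. No filter on dim genes was applied in the reported fit. Signal over background was not given in the sources used here, so a small difference of a dim gene is not evidence that the gene did not change.

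Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). The adiponectin effect was the treatment term beside time point as a block of 5 levels (4 residual degrees of freedom), so every treated culture was set against the control of its own time. The pairing thus comes from the time points in the labels. Differences between treated and control correlated across genes between pairs at 0.11 to 0.64 (genes are not independent replicates). The change of the effect with time was the treatment by log2 hours term added to that model (3 residual degrees of freedom). Time in culture was the log2 hours term beside treatment (7 residual degrees of freedom), without a block, so the 2 arrays of a time counted as independent. Errors shared by such a pair would make its p values too small, and the slope was also fitted to the mean of the 2 arrays of each time (3 residual degrees of freedom). Means over times are given with the SD over the 5 pairs.

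Before the data were examined, the tests, all but 1 of their alternatives, 32 gene lists and the rule for naming genes were fixed. The lists cover inflammatory cytokines and chemokines, the NF-kB pathway, lipopolysaccharide-inducible effector and tolerance genes, the type I interferon response, Toll-like receptor pathway components, osteoclast genes, osteoclastogenesis regulators, adiponectin receptors with AMPK or PPAR-alpha targets, alternative macrophage activation, vitamin D targets, cholesterol synthesis, LXR targets, glycolysis and hypoxia, NRF2 targets, the cell cycle and reference genes. Others mark osteoblasts, stromal cells, adipocytes, endothelium, neutrophil granules (primary and late), macrophages, monocytes, dendritic cells, B cells, plasma cells, T and NK cells, erythroid cells, megakaryocytes, mast cells with basophils and eosinophils, and progenitors. Lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. At single times, where each group has 1 array, a list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Genes were named by this rule: the 10 largest rises and falls past the threshold with the same sign in 5 of 5 pairs; at each time the 4 largest rises and 2 largest falls among genes above the median level; the 5 steepest slopes in each direction past the threshold; in each list the 4 members with the largest absolute mean change and those past the threshold; and a fixed set of receptor, cytokine and osteoclast genes.

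The tests were checked on simulated data of 19938 genes, with 100 genes changed per size. For the adiponectin effect, 97% of genes changed by a log2 difference of 1 and 100% of those changed by 2 were called, with 2.96% false calls. For the change of the effect with time, 87% of slopes of 0.5 per doubling and 98% of slopes of 1 were called, with 2.12% false calls. For time in culture the shares were 97% and 100%, with 2.96% false calls. In the check of camera, the 1 shifted list was called and 0 of 31 others. Noise was drawn independently for each gene in all these simulations. They therefore cannot show how camera or the shares of false calls behave when genes are correlated. The shares called hold for the simulated sizes and numbers of changed genes, because the adjusted p depends on how many genes change. Alternatives were quantile normalization repeated, centring of each array on its median, leaving out the lowest 40% of genes by mean value, the mean of a gene's probe sets, an intensity trend with a robust prior, a test without moderation, no block, log2 hours in place of the block, late against early times, control arrays alone, the mean of the 2 arrays of each time (chosen after the results were seen), an exact sign-flip permutation test over the pairs, and leaving out each time point in turn. Figures were drawn with matplotlib 3.10.9.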

Results

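Bone marrow cells flushed from the long bones of young male Swiss mice were cultured with calcitriol, the active form of vitamin D, which lets osteoclasts, the bone-resorbing cells of the macrophage lineage, form from marrow precursors. The cultures received recombinant mouse adiponectin, a hormone secreted by fat cells, at 5 µg/ml, or vehicle. RNA from 1 vehicle (control) culture and 1 adiponectin culture was hybridised to an array at each of 4, 10, 24, 72 and 120 h, which gives 10 arrays in 5 pairs. The title of the series names contamination with lipopolysaccharide, the bacterial endotoxin that activates Toll-like receptor 4, so the comparisons ask which genes differed between treated and control cultures and how those differences ran over time. Array medians over the 19938 named genes lay between 8.27 (the 10 h control) and 8.48 (the 24 h control) on the log2 scale. The number of arrays limits the precision of every value. The labels do not say whether the cultures came from separate animals, so p-values measure only the spread between these cultures, which may be technical. With 1 pair per time, that spread and each SD over pairs also hold any change of the effect with time.

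Chemokine, acute-phase and interferon-induced genes made up the largest rises in adiponectin cultures. The largest mean rise was that of Ccl5, a chemokine that attracts T cells and monocytes, at 3.47 ± 0.52 on the log2 scale (mean over times ± SD, n = 5 pairs; 11.1-fold; limma adjusted p = 1.14e-06; higher in 5 of 5 pairs). Cfb, the complement factor B gene, rose by 3.22 ± 0.73, Acod1, the enzyme that makes itaconate in activated macrophages, by 3.04 ± 0.43, and Saa3, an acute-phase serum amyloid, by 2.88 ± 0.73 (adjusted p = 9.43e-06, 1.14e-06 and 2.05e-05). The antiviral genes Ifit3b (3.33 ± 0.73), Ifit2 (2.996 ± 0.54), Ifit1 (2.88 ± 0.54), Ifit3 (2.80 ± 0.59) and Ifi205 (2.80 ± 0.66) and the interferon-induced chemokine Cxcl9 (2.79 ± 0.81) completed the 10 largest rises, each higher in 5 of 5 pairs. Of 19938 genes, 408 rose and 74 fell at an adjusted p under 0.05. Among the 408, 400 were higher in 5 of 5 pairs, 120 rose at least 2-fold and 31 at least 4-fold. Of the 74, 73 were lower in 5 of 5 pairs and 2 fell at least 2-fold. At an unadjusted p under 0.05 the counts were 1178 and 840, but 1151 and 1469 after repeated quantile normalization and 1035 and 1086 with each array centred on its median, so which direction held more genes there depended on the scaling. Over all 19938 genes, 1261 were higher and 877 lower in 5 of 5 pairs, where chance gives 3.125% of genes for each. Without the time point as a block, that is without pairing, 146 and 4 genes passed, and an ordinary test of the same model, without moderation, called 9 and 0. The count of genes that fell also depended on single pairs: 46 without the 10 h pair and 21 without the 24 h pair. It depended on scaling and model as well. At an adjusted p under 0.05, 360 rose and 113 fell after repeated quantile normalization. With an intensity trend and robust prior the counts were 420 and 117, and with log2 hours in place of the block 283 and 30.

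Cd209a, a C-type lectin of monocyte-derived dendritic cells, fell by the largest amount among the called genes, -2.36 ± 0.54 on the log2 scale (5.14-fold lower; adjusted p = 1.36e-05; lower in 5 of 5 pairs). The lipid transporter gene Abca9 fell (-1.10 ± 0.42; adjusted p = 0.000918), as did Nxpe5 (-0.94 ± 0.60; 0.0167), the lectin gene Cd209d (-0.90 ± 0.28; 0.000559) and Gas6, a ligand of the TAM receptors (-0.89 ± 0.62; 0.0279). Atp6v0d2, a subunit of the osteoclast proton pump that is needed for cell fusion, fell by 0.91 ± 0.43 (adjusted p = 0.00346). Cd28 (-0.85 ± 0.25), Bex1 (-0.85 ± 0.42), Gm14461 (-0.75 ± 0.38) and the lysosomal transporter Slc46a3 (-0.74 ± 0.40) made up the rest of the 10 largest falls, with adjusted p of 0.000492, 0.00500, 0.00672 and 0.0105. Calls lost when 1 time was left out, with the adjusted p then, were those of Nxpe5 (without 4, 10 or 24 h, up to 0.104), Gas6 (without 4, 10 or 24 h, up to 0.113) and Slc46a3 (without 24 h, 0.0696).

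Interferon-response genes moved together. Of 40 measured members, 39 rose (40 adjusted over the list alone), with a median mean difference of 1.85. The member that did not pass was Cxcl11, named here after its values were seen (0.49 ± 0.40; adjusted p = 0.0947). Alongside the Ifit genes and Cxcl9, Cxcl10 rose by 2.74 ± 0.96, Mx1 by 2.71 ± 0.49, Rsad2 by 2.65 ± 0.29 and Usp18 by 2.63 ± 0.25. The transcription factor genes Irf7, Stat2 and Irf1 rose by 1.76 ± 0.44, 1.51 ± 0.21 and 0.79 ± 0.26. By camera the list rose (adjusted p = 1.78e-112, and adjusted p = 0.0323 with an estimated correlation). Ifnb1, which encodes interferon beta itself, differed by 0.07 ± 0.22 (limma adjusted p = 0.887), with its largest difference, 0.35, at 4 h. Its values of 6.40 to 6.80 lay below the array medians of 8.27 to 8.48, so the small difference does not show that it was not induced.

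Of 30 measured genes for inflammatory cytokines and chemokines, 16 rose (22 adjusted over the list alone) and 0 fell. Ccl12 (1.15 ± 0.87), Il1b (1.10 ± 0.44), Tnf (0.96 ± 0.60) and Ccl7 (0.93 ± 0.35) followed Ccl5, and Il6 (0.80 ± 0.50), Il12b (0.88 ± 0.62), Cxcl2 (0.90 ± 0.69), Il18 (0.89 ± 0.52) and Ccl2 (0.84 ± 0.47) rose as well. By camera the list rose (adjusted p = 1.02e-24, and adjusted p = 0.130 with an estimated correlation). Effector and tolerance genes that lipopolysaccharide induces in macrophages rose as a list under both settings (adjusted p = 4.76e-22, and adjusted p = 0.0193 with an estimated correlation), with 14 of 33 members up and 22 adjusted over the list alone. Besides Cfb, Acod1 and Saa3, they included Slfn4 (2.28 ± 0.75), the scavenger receptor Marco (2.04 ± 0.30), Gpr84 (1.26 ± 0.68), Clec4e (1.09 ± 0.53), the anti-inflammatory cytokine Il10 (0.89 ± 0.45) and the feedback inhibitor Socs1 (0.78 ± 0.52). Nos2, the inducible nitric oxide synthase, differed by 0.97 ± 0.79 (adjusted p = 0.0560), Ptgs2 by 0.51 ± 0.39 (0.0771) and Cd14, the lipopolysaccharide co-receptor, by 0.55 ± 0.46 (0.0942), each short of the threshold. Leaving out 1 time ended the calls of Ccl12 (without 4, 24 or 120 h, up to 0.113), Il6 (without 24 h, 0.0767), Il12b (without 4, 10 or 24 h, up to 0.130), Cxcl2 (without 4, 10 or 120 h, up to 0.157), Il18 (without 10, 24 or 120 h, up to 0.0802) and Socs1 (without 4, 10 or 24 h, up to 0.147), in adjusted p.

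The NF-kB pathway and its feedback genes rose by camera (adjusted p = 9.71e-16, and adjusted p = 0.243 with an estimated correlation). Ikbke (0.71 ± 0.09), Tnip3 (0.67 ± 0.34) and Cflar (0.65 ± 0.20) were the 3 of 26 members to pass over all genes, against 18 adjusted over the list alone. Cd40 (0.88 ± 0.82, limma adjusted p = 0.101) and Sod2 (0.67 ± 0.52, limma adjusted p = 0.0584) had similar means and larger spreads. These spreads hold differences between times. From 4 to 120 h Cd40 was at 2.06, 1.23, 0.90, 0.06 and 0.15, and Sod2 at 1.11, 1.18, 0.83, 0.04 and 0.20. Among Toll-like receptor pathway components, 6 of 24 rose (7 adjusted over the list alone): Tlr3 (1.14 ± 0.28), Tlr9 (1.10 ± 0.19), Irak3, an inhibitory kinase of the pathway (0.81 ± 0.05), Tlr2 (0.70 ± 0.47), Tlr7 (0.36 ± 0.16) and Myd88 (0.32 ± 0.10). The list rose by camera (adjusted p = 0.00282, and adjusted p = 0.130 with an estimated correlation), with a median of 0.05. The calls of Tlr2 (without 10 or 24 h, up to 0.108), Tlr7 (without any 1 time, up to 0.194) and Myd88 (without any 1 time, up to 0.141) were lost with 1 time left out, as adjusted p. Tlr4 itself (0.00 ± 0.34, limma adjusted p = 0.999) and its partner Ly96 (0.06 ± 0.13, limma adjusted p = 0.896) showed mean differences near 0. From 4 to 120 h Tlr4 was at -0.55, 0.12, -0.11, 0.29 and 0.25, so its mean covers values of both signs.

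**Figure D1:**
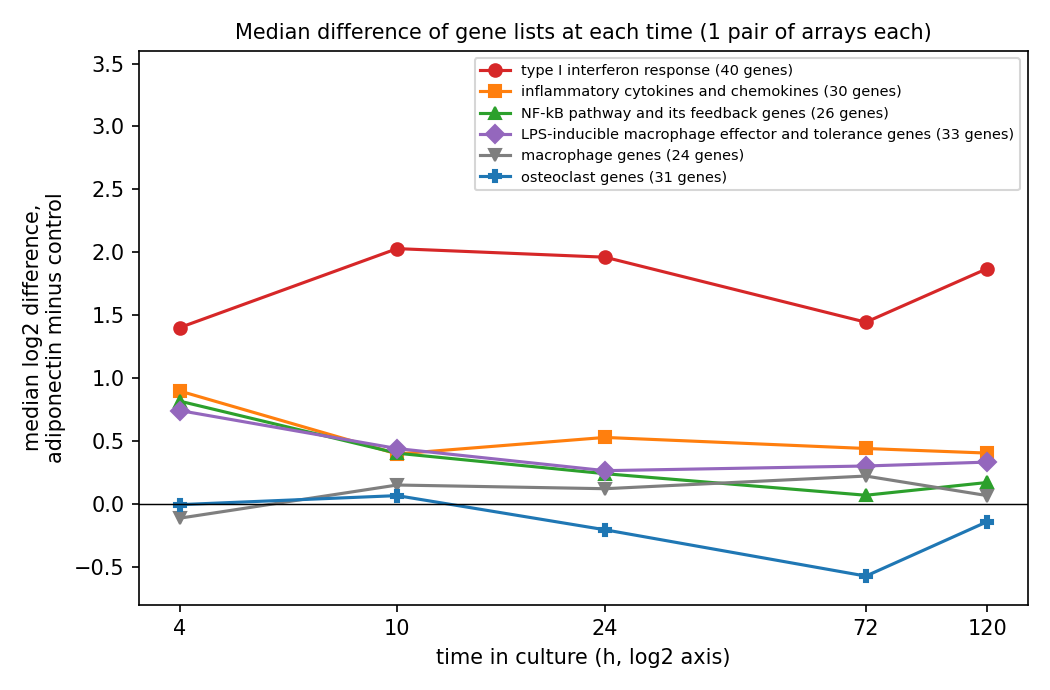
Median log2 difference (vertical axis, adiponectin minus control) of 6 gene lists against time in culture (horizontal axis, hours on a log2 axis), 1 pair of arrays per point. The interferon list stays between 1.40 and 2.03, the NF-kB list drops from 0.82 at 4 h to 0.07 at 72 h, and the osteoclast list reaches -0.57 at 72 h.

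None of the adiponectin receptor genes passed the test. Adipor1 differed by -0.04 ± 0.09 (adjusted p = 0.938), Adipor2 by -0.09 ± 0.13 (0.820) and Cdh13, which encodes T-cadherin, by -0.09 ± 0.32 (0.890). Over 20 genes of the receptors and of AMPK or PPAR-alpha targets, the median was -0.06, and 1 rose and 0 fell over all genes (1 and 1 adjusted over the list alone). The gene that rose was the fatty acid binding protein Fabp3 (0.63 ± 0.38; adjusted p = 0.0204), while Pdk4 was at -0.66 ± 0.55 (0.0772), Angptl4 at -0.26 ± 0.19 and Acadm at -0.22 ± 0.12. By camera the list fell (adjusted p = 0.0125, and adjusted p = 0.334 with an estimated correlation). Among adipocyte genes, the median was -0.09 and 1 of 15 fell (3 adjusted over the list alone): Pparg, the main transcription factor of fat cells, at -0.53 ± 0.36 (adjusted p = 0.0475). Adipoq differed by -0.43 ± 0.44 (0.204) and Lpl by -0.37 ± 0.24 (0.0837). The adipocyte list fell by camera (adjusted p = 0.00472, and adjusted p = 0.243 with an estimated correlation). With 1 time left out, the calls of Fabp3 (without 10 or 24 h, up to 0.103) and Pparg (without 4, 10 or 24 h, up to 0.216) and of the receptor and AMPK list (without 4 h, 0.0517) were lost, as adjusted p.

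Osteoclast genes were lower on average in the treated cultures. Of 31 members, 1 fell over all genes, Atp6v0d2, and 4 fell adjusted over the list alone; the median mean difference was -0.24. Ctsk, the collagen-degrading protease of osteoclasts, differed by -0.45 ± 0.64 (adjusted p = 0.412), Dcstamp, needed for cell fusion, by -0.54 ± 0.89 (0.525), Oscar by -0.46 ± 0.88 (0.625), Slc9b2 by -0.55 ± 0.98 (0.570), Nfatc1 by -0.24 ± 0.23 (0.343), the calcitonin receptor Calcr by -0.24 ± 0.55 (0.749) and Acp5, the tartrate-resistant phosphatase, by -0.01 ± 0.46 (0.995). The list fell by camera (adjusted p = 2.27e-06, and adjusted p = 0.384 with an estimated correlation). Among regulators of osteoclast formation, 2 of 16 rose (3 adjusted over the list alone), Il15 by 0.76 ± 0.17 and Tnfrsf1b by 0.60 ± 0.27, and the list rose by camera (adjusted p = 0.0373, and adjusted p = 0.243 with an estimated correlation). Tnfsf11, which encodes RANKL, differed by 0.01 ± 0.17 (adjusted p = 0.981), its decoy receptor Tnfrsf11b by 0.09 ± 0.20 (0.841) and Irf8, a repressor of osteoclast formation, by 0.22 ± 0.20 (0.389). The call of the regulator list was lost with 1 time left out (adjusted p without 4, 72 or 120 h, up to 0.168).

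**Figure D2:**
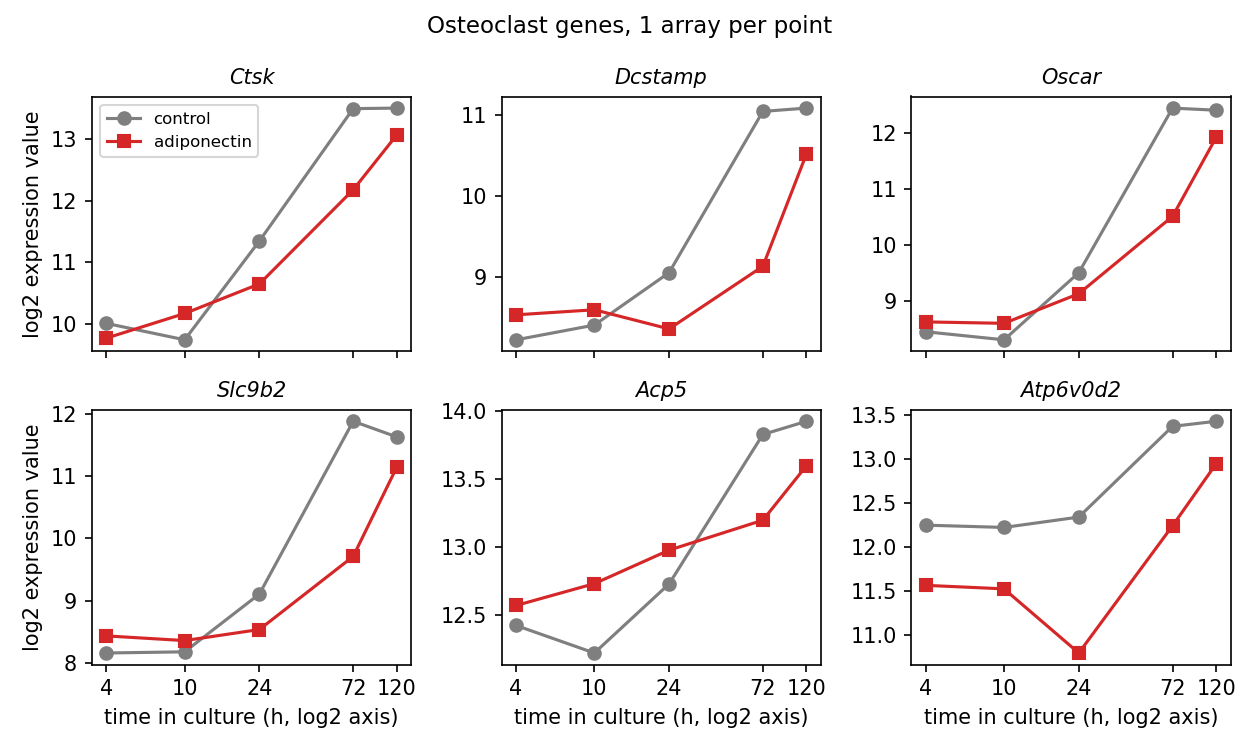
Log2 expression values (vertical axes) of 6 osteoclast genes against time in culture (horizontal axes, hours on a log2 axis) in control (grey) and adiponectin (red) cultures, 1 array per point. At 72 h the treated value lies below the control for each of the 6 genes, with differences of -2.17 for Slc9b2 and -0.63 for Acp5.

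The macrophage and monocyte lists did not pass as lists, while single members rose. Among 24 macrophage genes the median was 0.05; 3 rose and 0 fell (5 and 1 adjusted over the list alone), with the Fc receptor Fcgr1 at 0.98 ± 0.48 (adjusted p = 0.00363), Siglec1 at 0.87 ± 0.37 (0.00223), Ms4a7 at 0.30 ± 0.06 (0.0498) and the mannose receptor Mrc1 at -0.64 ± 0.56 (0.0903). Of 12 monocyte genes, with a median of 0.01, 4 rose and 0 fell (4 and 1 adjusted over the list alone). Those that rose were Plac8 (1.43 ± 1.09), Ms4a6b (1.07 ± 0.46), Treml4 (0.50 ± 0.29) and Ms4a6c (0.37 ± 0.14). Ccr2 was at -0.40 ± 0.41 (limma adjusted p = 0.229). Camera adjusted p was 0.120 for the macrophage and 0.143 for the monocyte list. Dendritic cell and MHC class II genes fell by camera (adjusted p = 0.00811, and adjusted p = 0.454 with an estimated correlation), with 1 of 18 down, Cd209a, and 1 up, the costimulatory gene Cd86 (0.51 ± 0.24; adjusted p = 0.0154); adjusted over the list alone, 8 fell and 3 rose. Itgax differed by -0.65 ± 0.73 (0.217) and H2-Aa by -0.55 ± 0.43 (0.0703). Alternative activation markers had a median of -0.03 and 0 of 14 rose and 0 fell over all genes (1 and 3 adjusted over the list alone). The calls of Ms4a7 (without any 1 time, up to 0.252), Plac8 (without 10, 24 or 72 h, up to 0.153), Treml4 (without 4, 10, 72 or 120 h, up to 0.0872), Ms4a6c (without 10, 24, 72 or 120 h, up to 0.118) and Cd86 (without 4 or 10 h, up to 0.0665) were lost with 1 time left out, as adjusted p.

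T cell and NK cell genes rose as a list by camera (adjusted p = 0.00472, and adjusted p = 0.334 with an estimated correlation). Over all genes 0 of 19 rose and 1 fell, Cd28; adjusted over the list alone, 7 rose and 2 fell. Gzmb, which encodes a cytotoxic granule protease, differed by 1.51 ± 1.36 (adjusted p = 0.0804), Il2rb by 0.79 ± 0.88 (0.203) and Cd3g by 0.45 ± 0.32 (0.0713). Late granule genes of neutrophils fell by camera (adjusted p = 0.000142, and adjusted p = 0.334 with an estimated correlation), with 0 of 21 members down over all genes and 5 adjusted over the list alone, and primary granule genes had a median of 0.02 (camera adjusted p = 0.443). Stromal (-0.06; camera adjusted p = 0.00841, and adjusted p = 0.257 with an estimated correlation), erythroid (-0.06; 0.00811, and adjusted p = 0.243 with an estimated correlation) and megakaryocyte genes (-0.11; 0.00875, and adjusted p = 0.454 with an estimated correlation) fell as lists by small medians, and no member of these 3 lists passed over all genes. The lists for osteoblasts (-0.01), endothelium (-0.09), B cells (0.00), plasma cells (0.03), mast cells with basophils and eosinophils (0.01) and progenitors (-0.07) did not pass. Single members of them did: Kdr (0.66 ± 0.35) and Cd72 (0.84 ± 0.27) rose and Ear6 (-0.48 ± 0.23) fell. List calls lost with 1 time left out, as adjusted p, were those of T cell and NK cell (without 120 h, 0.0589), stromal (without 4 h, 0.0517), erythroid (without 120 h, 0.0589) and megakaryocyte genes (without 10 or 24 h, up to 0.0922), and gene calls those of Kdr (without 24 h, 0.0750) and Ear6 (without 4, 72 or 120 h, up to 0.0812).

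Among metabolic lists, glycolysis and hypoxia genes rose by camera (adjusted p = 0.000131, and adjusted p = 0.110 with an estimated correlation), with Pfkfb3 (0.54 ± 0.18) and Hif1a (0.31 ± 0.09) the 2 of 18 members past the threshold and 5 adjusted over the list alone. Of 10 LXR targets, with a median of -0.07, 2 rose and 0 fell over all genes (2 and 1 adjusted over the list alone). Nr1h3, which encodes LXR-alpha, rose by 0.60 ± 0.03 with nearly the same value in each pair, and the cholesterol exporter Abca1 by 0.33 ± 0.12. Lpl, also a member, was at -0.37 ± 0.24, and the list did not pass (camera adjusted p = 0.443). Cholesterol synthesis (-0.07), NRF2 (0.09), vitamin D target (0.04) and reference genes (-0.07) had medians near 0 and did not pass. Cell cycle genes fell by camera (median -0.06; adjusted p = 0.0373, and adjusted p = 0.629 with an estimated correlation), with no member past the threshold. That list's call (without 4, 24 or 72 h, up to 0.808) and those of Abca1 (without 4, 10, 24 or 72 h, up to 0.164) and Hif1a (without any 1 time, up to 0.160) were lost with 1 time left out, as adjusted p. In all, 17 of 32 lists passed with the preset correlation, 8 up and 9 down, and 2 with an estimated one, the interferon and lipopolysaccharide-inducible lists. Other divisions of the 10 arrays into groups of 5 also gave up to 17 called lists with the preset correlation.

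At single time points no test was possible, because each time has 1 array per group, and the following are values of those pairs. At 4 h Cxcl10 was 4.29 higher on the log2 scale, Ccl5 3.76, Acod1 3.67 and Gbp5 3.56, and Cd209a (-2.13) and the lectin Clec10a (-1.42) were lowest. Tnf (1.99), Il1b (1.87) and Il6 (1.53) also had their largest differences at 4 h. At 10 h Ifit3b (4.37), Ccl5 (4.04), Ifit2 (3.59) and Cfb (3.50) led, with Cd209a (-1.72) and Scarna17 (-1.61) lowest at this time. The median of all genes differed by 0.07 at 10 h, where the control array had the lowest median of the 10, and by -0.07 after each array was centred on its median. At 24 h Cxcl9 (4.08), Cfb (3.92), Ccl5 (3.69) and Ifit3b (3.62) led, with Cd209a (-3.16) and Abca9 (-1.68) lowest. At 72 h Saa3 (3.77), Cfb (3.52), Ccl5 (3.03) and Gzmb (2.82) led, with Cd209a (-2.58) and Slc9b2 (-2.17) lowest. At 120 h Igkv9-120, an immunoglobulin segment, stood at 4.38, Ifi205 at 3.91, Ms4a4c at 3.82 and Saa3 at 3.56, with Cd209a (-2.23) and Mamdc2 (-1.59) lowest. Genes at least 2-fold higher numbered 145, 178, 170, 109 and 150 from 4 to 120 h, and those at least 2-fold lower 24, 26, 45, 31 and 6.

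The interferon list had medians of 1.40, 2.03, 1.96, 1.44 and 1.87 at 4, 10, 24, 72 and 120 h, each above the 10000 random lists of matched expression drawn for it (percentile 100). Cytokines and chemokines stood at 0.90 at 4 h and between 0.40 and 0.53 later (percentile 100 at each time). NF-kB genes were at 0.82, 0.40, 0.24, 0.07 and 0.17, with percentiles of 100, 100, 100, 96.5 and 99.95. Osteoclast genes were at -0.01, 0.07, -0.21, -0.57 and -0.14, with percentiles of 91.2, 69.2, 0.08, 0 and 0. At 72 h Dcstamp was at -1.91, Oscar at -1.93, Ctsk at -1.32, Calcr at -1.11 and Acp5 at -0.63; at 120 h the same genes were at -0.57, -0.48, -0.44, -0.45 and -0.33. T cell and NK cell genes were at 0.09, 0.00, 0.36, 0.25 and 0.31 (percentiles 33.6, 6.23, 99.99, 100 and 100). Cell cycle genes were at -0.21, 0.04, -0.27, -0.08 and 0.34 (percentiles 0.34, 23.9, 0.04, 0.57 and 100). Reference genes, with medians of -0.10 and -0.09 at 72 and 120 h, also reached low percentiles there, 1.45 and 0.2. The random lists do not carry the correlation between members of a list. These percentiles are therefore not p-values, and an extreme one can come with a small median.

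Whether the adiponectin effect rose or fell over the culture was tested as its slope on log2 hours. The effect is taken with its sign here, so a fall can be a shrinking rise, a growing deficit or a change from a rise to a deficit. No gene passed with limma in either direction, and dropping single pairs gave at most 1 gene. At an unadjusted p under 0.05, 620 effects rose and 1339 fell, but 803 and 673 after repeated quantile normalization, 1058 and 625 with each array centred on its median and 551 and 503 without the lowest 40% of genes, so the excess of falling effects depended on the setting. Tnf had a slope of -0.22 per doubling of time (adjusted p = 0.499), Ccl5 -0.23 (0.438) and Gzmb 0.64 (0.0764). The slope of Gzmb exceeded the 0.5 used in the simulation and was still not called. The lack of called genes thus does not show that no effect changed with time. By camera 9 of 32 lists passed, 5 up and 4 down, against 0 with an estimated correlation and 14 without the 120 h pair. The effect on NF-kB genes, cytokines, osteoclast genes, and dendritic cell and MHC class II genes fell with time (adjusted p = 3.71e-08, 0.000167, 0.000527 and 0.00325, and adjusted p = 0.569, 0.685, 0.766 and 0.569 with an estimated correlation). For NF-kB genes and cytokines a rise became smaller. The osteoclast medians instead went from -0.01 and 0.07 at 4 and 10 h to -0.21, -0.57 and -0.14 later. Those of dendritic cell and MHC class II genes went from 0.05 and 0.19 to -0.20, -0.21 and -0.23. The effect on T cell and NK cell, cell cycle, macrophage, primary granule and monocyte genes rose (adjusted p = 6.65e-06, 2.87e-07, 0.000101, 0.000417 and 0.0244, and adjusted p = 0.537, 0.739, 0.569, 0.537 and 0.685 with an estimated correlation). Adjusted over the list alone, the falling effects numbered 12, 4, 0 and 4 in the first 4 lists, and the rising effects 5 (with 1 falling), 0, 1, 4 and 3 in the 5 others, so no single osteoclast or cell cycle gene passed. For the cytokines the fall rested on the 4 h pair, without which the camera adjusted p was 0.714 in the other direction. The calls for NF-kB (without 4 h, 0.0842), monocyte (without 4 or 24 h, up to 0.121) and cell cycle genes (without 120 h, 0.591) were lost with 1 time left out, as adjusted p.

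Time in culture was the other factor of the design. The steepest rises per doubling of time among genes past the threshold were those of the anion transporter Slc26a7 (0.86 ± 0.07, SE; adjusted p = 3.48e-05), the natriuretic peptide receptor Npr3 (0.86), Oscar (0.81), Stc1 (0.77) and the Wnt antagonist Sfrp1 (0.77). Alas2, the first enzyme of haem synthesis in red cell precursors, fell by 1.08 ± 0.07 (SE; adjusted p = 2.51e-05), followed by Mmrn1 (-0.94), Ly6g (-0.94), F2rl2 (-0.92) and Slc14a1 (-0.89). Over both treatments 1956 genes rose and 1728 fell with log2 hours (limma adjusted p under 0.05). The balance turned to 1657 and 2300 with each array centred on its median and to 1392 and 1597 without the 10 h pair. This model takes the control and treated arrays of a time as independent. With the mean of the 2 arrays of each time, an alternative chosen after the results were seen, 985 genes rose and 974 fell, and control arrays alone gave 513 and 490. Without the 72 h pair the counts were 1259 and 1112, and without the 120 h pair 674 and 650.

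Osteoclast genes rose with time as a list (camera adjusted p = 3.41e-08, and adjusted p = 0.341 with an estimated correlation), 17 of 31 past the threshold (21 adjusted over the list alone), among them Ctsk (0.77 per doubling; adjusted p = 9.74e-05), Slc9b2 (0.69), Dcstamp (0.50) and Acp5 (0.28). Stromal genes rose as well, 14 of 21 (16 adjusted over the list alone; camera adjusted p = 6.65e-05, and adjusted p = 0.341 with an estimated correlation), with Kitl (0.55) and Cxcl12 (0.51), and so did osteoblast genes, 7 of 19 (7 adjusted over the list alone; camera adjusted p = 0.000574, and adjusted p = 0.262 with an estimated correlation), with Ogn (0.60). Genes of the cells that fill fresh marrow fell. Of late granule genes of neutrophils, 20 of 21 fell, such as Camp (-0.85), and of primary granule genes 9 of 11. Among B-lineage genes 15 of 22 fell, among erythroid genes 11 of 18, among megakaryocyte genes 9 of 11, such as Itga2b (-0.62), and among cell cycle genes 17 of 29. Adjusted over the list alone, the falls in these 6 lists numbered 20, 9, 15, 14, 10 and 21. Camera called the 6 lists down (adjusted p = 1.28e-18, 9.68e-10, 6.97e-14, 9.26e-11, 4.46e-09 and 1.80e-13 in that order, and adjusted p = 0.254, 0.122, 0.254, 0.122, 0.254 and 0.282 with an estimated correlation). It also called down the mast cell with basophil and eosinophil, progenitor, dendritic cell and MHC class II, cytokine, NF-kB, lipopolysaccharide-inducible, Toll-like receptor pathway and cholesterol lists (adjusted p = 3.72e-05, 0.00128, 0.00662, 0.0442, 0.000163, 0.00543, 0.0155 and 0.000574, and adjusted p = 0.254, 0.254, 0.442, 0.608, 0.442, 0.442, 0.442 and 0.442 with an estimated correlation). The calls for cytokines (without 120 h, 0.395), lipopolysaccharide-inducible (without 120 h, 0.269) and Toll-like receptor genes (without 4 h, 0.135) were lost with 1 time left out, as adjusted p, and so was that of Dcstamp (without 120 h, 0.0683). In all, 3 lists rose and 14 fell with the preset correlation, and 0 passed with an estimated one.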

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

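The tests of explanations for the 3 patterns weighed here and the comparison with divisions that part all pairs, for genes, were chosen only after the results were seen, whereas the 100 random divisions of the arrays and the comparison for lists were planned.

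Inflammatory and interferon genes were higher in adiponectin cultures from 4 h on, and the cytokine, NF-kB, lipopolysaccharide-inducible and interferon lists all lay above the 95th percentile of matched random lists at 4 h (4 of 4). That restates the pattern, so it does not count for a Toll-like receptor 4 ligand in the protein preparation, the contamination the series title names. This source and the adiponectin protein itself cannot be told apart, because the arrays hold neither lipopolysaccharide alone nor a preparation freed of it. A larger share of macrophages is argued against as the whole account of the interferon rise. The macrophage list had a median of 0.0542 against 1.85 for the interferon list. A part of the rise stays open, because the macrophage list lay at percentiles 10.7, 99.1, 99.8, 100 and 88.95 from 4 to 120 h. Its members also went both ways (Fcgr1 0.98 and Siglec1 0.87, Mrc1 -0.64 and Vsig4 -0.52), so its median is a limited measure of macrophage number. Signalling through adiponectin receptors to AMPK or PPAR-alpha stays open, because the list's median of -0.0606 does not exclude effects outside these transcripts.

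Osteoclast genes had their lowest differences at 72 h, with a median of -0.57 over 31 genes, 28 of them lower. A lower signal of every transcript in the treated 72 h array could not be tested, because normalization would remove a fall shared by all. In the normalized values the list median differed by -0.56 from the median of all genes (SE 0.114). The drop seen there was thus not one shared by most genes. Each SE in this paragraph is that of a mean over the 31 genes in single arrays, so it does not measure the spread between cultures. The 72 h control did not stand above the 120 h control (median difference -0.0279, SE 0.0403), but the treated arrays rose by 0.37 from 72 to 120 h, so a deviating 72 h pair stays open. Slower formation of osteoclasts was not decided. Of the 17 genes that rose with time in these same arrays, all 17 were lower at 72 h. In the treated 72 h array 12 of them (70.6%) lay between the 24 h and 72 h controls. A partial drop of any source would give such values. With 1 array per group at each time, these last 2 explanations stay open.

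Gzmb was 2.82 higher at 72 h and 2.89 at 120 h, and Il2rb 1.22 and 2.001. A larger number of T cells or NK cells could bring this about, but 10 lineage markers had a median late difference of 0.200 against 2.85 for Gzmb. The SE of 0.116 for the markers is that of a mean over the 10 genes, not over cultures. The markers went both ways, so the median hides rises of single ones. At 120 h Cd3g was at 0.92, Eomes at 0.87, Ncr1 at 0.84, Klrb1c at 0.42 and Cd3e at 0.31. Cd5 was at -0.45, Cd3d at -0.13, Zap70 at -0.12, Cd8a at -0.11 and Cd2 at -0.01. Averaged over the 5 controls, 0 of the 10 markers lay above the median level of all genes, so a small number of such cells would not be seen and the explanation stays open; no other was tested.

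Among 100 random divisions of the arrays into 5 and 5, the real one gave 408 genes in its larger direction, higher (highest other 23). It gave 74 in its smaller direction, lower, where the highest count in the smaller direction of another division was 17. For each count 1 of 100 reached it, the real one. Divisions that part the same pairs in the same way are the same fit, so the 100 are not all distinct. For lists with the preset correlation the real division gave 17 and 4 of 100 reached it, the highest other giving 17 as well. These divisions do not settle the role of chance, because 86 of the 100 part fewer than 5 pairs and so leave treatment differences in the residual. Among the 16 divisions that part all 5 pairs, the real one gave 408, 74 and 17 and the highest other 0, 0 and 15; 1 of 16 reached each, which is too few divisions for a share under 0.05. The other divisions put at least 1 treated culture among the controls.

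Of 166 sets of 5 pair differences, 11 had 1 time far from the other times, where chance gives about 1 in 20, or 8.3; the range at the other times stands in parentheses. At 4 h the differences were Il1b 1.87 (0.80 to 1.02), Ms4a6b 0.26 (1.16 to 1.37), Myd88 0.48 (0.23 to 0.29), Siglec1 0.23 (0.95 to 1.15), Tnf 1.99 (0.50 to 0.85) and the median of the list of inflammatory cytokines and chemokines 0.90 (0.40 to 0.53). At 24 h the differences were Egr2 -1.46 (-0.62 to -0.37), Ly96 0.29 (-0.04 to 0.04) and Mrc1 -1.62 (-0.53 to -0.28). At 120 h the differences were Adipor2 0.14 (-0.20 to -0.12) and Igkv9-120 4.38 (-0.32 to 0.38). Probe sets outside the comparisons also carried signal, tested in the same model: among those without a gene name 28 were higher and 5 lower with adiponectin, and among those with several names 35 were higher.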

How the results depend on the processing

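The mean of the 2 arrays of each time was added after the results were seen, and all other alternatives were planned. The adiponectin pairs come from the time points, and without that pairing (no block) 146 genes were higher and 4 lower, all among the 408 and 74; with log2 hours in place of the block 30 were lower, and the test without moderation called 9 and 0 (690 lower at an unadjusted p under 0.05). Other settings gave 283 to 420 higher genes, and leaving out 1 time 292 to 379. Counts of lower genes were 113 after repeated quantile normalization, 117 with an intensity trend and robust prior, and 21 to 62 without 1 time (46 without 10 h, 21 without 24 h). In the exact sign-flip test 1261 and 877 genes reached its smallest p, 0.0625. For the trend of the effect, an intensity trend with robust prior called 2 rising and 3 falling genes, and leaving out 1 time gave 0 to 1 rising. Time in culture called 513 and 490 genes in control arrays alone, 985 and 974 with the mean of the 2 arrays of each time, and 674 to 2127 and 650 to 1871 without 1 time (1259 and 1112 without 72 h, 674 and 650 without 120 h). With an estimated correlation 2, 0 and 0 lists passed for adiponectin, trend and time. Fry called 7 for adiponectin, 0 for the trend and 14 for time, and leaving out 1 time gave 8 to 14 trend lists. No gene was called in the opposite direction under any setting of the counts. The cause of these changes was not tested. Named genes whose mean difference changed sign without 1 time, none of them called, were Acp5 -0.14 to 0.14, Cdh13 -0.17 to 0.0201, Tlr4 -0.0740 to 0.14 and Tnfsf11 -0.0317 to 0.0610 (lowest to highest). Tnfsf11 also changed sign, to -0.00398 (quantile-normalized again) and -0.00331 (each array centred on its median). The camera adjusted p of the cytokine list for the trend ran from 4.54e-07 to 0.714 without 1 time, the latter in the other direction, without 4 h. Of other values for named genes and lists, 1368 gene values for adiponectin kept their direction and side of the threshold, 304 fell short of it and 17 newly passed, 347 list calls were kept and 99 lost, and 265 of the time slopes kept theirs (1 lost); 424 list medians at single times stayed within 1 standard error over their genes and 56 moved by more. Centring each array moved the median of all genes at 10 h from 0.07 to -0.07, so values near that size at 10 h have no settled direction. The share of calls that were higher was 84.6%, 76.1% and 79.1% as deposited, quantile-normalized again and centred.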

Other observations

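The genes and families described here were chosen after their values were seen, and the tests on them are those of the adiponectin comparison. Of the guanylate-binding protein genes, 8 of 8 passed the limma threshold as higher, and of the schlafen genes 8 of 9, with medians at 24 h of 1.67 and 1.17. These counts repeat in part the fixed lists, which hold Gbp2, Gbp3, Gbp5 and Slfn4. Single genes with known roles in presenting peptides on MHC class I were among the called rises, picked from these and not tested as a group: the immunoproteasome subunits Psmb8 (0.87 ± 0.35; adjusted p = 0.00192) and Psmb10 (0.83 ± 0.32; 0.00156), the proteasome activator Psme1 (0.43 ± 0.12; 0.0109), the transporter subunit Tap2 (0.42 ± 0.15; 0.0157) and the class I genes H2-T24 (1.66 ± 0.35; 1.51e-05) and H2-Q4 (1.04 ± 0.48; 0.00254). Other single genes picked from the called rises, also with no test as groups, were the inflammasome genes Casp1 (0.65 ± 0.17), Casp4, the cytosolic receptor for lipopolysaccharide (0.80 ± 0.22), Nlrc4 (0.61 ± 0.23) and Aim2 (0.33 ± 0.09). So were Cd274, which encodes PD-L1 (1.36 ± 0.36), Tnfsf10, which encodes TRAIL (1.80 ± 0.51), and the chemokine Ccl8 (1.99 ± 1.16). Mir146, the gene of a microRNA that restrains Toll-like receptor signalling, rose by 0.80 ± 0.14 (limma adjusted p = 0.000153).

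Further genes that fell included Gpr183, a receptor for oxysterols (-0.74 ± 0.28; adjusted p = 0.00223), the transcription factor Egr2 (-0.72 ± 0.43; 0.0165), the chemokine receptor Ccr1 (-0.37 ± 0.16; 0.0405), the elastase Mmp12 (-0.50 ± 0.32; 0.0392) and the selenium carrier Selenop (-0.33 ± 0.05; 0.0293). None of the 10 granzyme genes passed with limma over all times. Their median was 0.54 at 72 h and 1.20 at 120 h, with Gzmc at 1.76 and 2.69 and Gzmd at 1.95 and 3.50, single pairs without a test. The immunoglobulin joining chain Jchain was at 1.57 and 1.498, and 8 kappa variable genes had a median of 0.67 at 120 h. Of 55 small nucleolar RNA genes 1 fell, and their median was -0.37 at 24 h and -0.01 at 120 h. H2-Aa was at -1.12 and H2-Ab1 at -0.99 at 120 h, 2 single genes. Calls lost with 1 time left out, as adjusted p, were those of Psme1 (without 24 h, 0.0523), Tap2 (without 10, 24 or 120 h, up to 0.0746), Aim2 (without any 1 time, up to 0.157), Ccr1 (without 4, 24, 72 or 120 h, up to 0.148), Mmp12 (without 10, 24, 72 or 120 h, up to 0.101) and Selenop (without any 1 time, up to 0.124).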
